A study of Mus musculus with 2 samples.

How the data were processed

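Total RNA of regulatory T cells (Tregs), the CD4+ T cells that express the transcription factor Foxp3 and restrain immune responses, was measured on Affymetrix mouse 3′ expression arrays. Per the labels' protocols, the cells came from spleens of 10-week-old animals on the C57BL/6 background and were purified by flow cytometry, and the RNA was labelled with biotin. There was 1 array from mice that carry a dominant negative TGF-beta receptor II (DNR) and 1 from wild-type (WT) mice. How many mice gave each RNA and how Foxp3 was detected in living cells are not given in the sources used here.

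The deposited table holds 1 signal intensity per probe set and array on a linear scale, made by the authors with MAS5 per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 value. The scaling is not described in the sources used here, but with the highest and lowest 2% of values left out both arrays had a mean of 500.0, so the arrays had been scaled to a common mean before deposition. Scaling of this kind multiplies background together with signal, so it raises the dimmest values of an array whose specific signal was weak. Detection calls, scanner values and other versions of the table were not used here.

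Of 45101 probe sets, 64 control probe sets were set aside, which left 45037. An annotation of the platform gave, over all of its entries, exactly 1 gene to 34958 probe sets and several genes to 932. Of the 45037 probe sets used, 9160 were not listed in it. In all, 10092 of the 45037 had no single gene name and are unnamed here. Current symbols were looked up through the Entrez identifier, which was found for 34754 of the 34958, and 0 symbols changed. No genome build is named in the sources, so no coordinates are given.

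The higher of the arrays' medians over the 45037 probe sets, a signal of 110.9, served as a floor, and lower values were set to it before log2 was taken. Each gene was represented by its probe set with the highest mean signal over both arrays. A gene was called measured if that probe set was above the floor on at least 1 array, which held for 11927 of 18193 genes: 9281 on both arrays, 1813 on the DNR array alone and 833 on the WT array alone. For genes above the floor on 1 array the ratio is a lower bound and is written as "at least". The log2 ratio is that of the DNR over the WT array.

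With 1 array per genotype no test of a difference between genotypes can be made, so no p-value, standard deviation or standard error is given. A change was described by size, with a threshold of 2-fold. For each of 29 gene lists the median log2 ratio of the measured members was set against 10000 random lists of the same size, drawn from measured genes matched on mean log2 signal in 20 bins. The medians include genes at their bound. The resulting percentile describes these arrays and not the genotypes. Random lists were drawn gene by gene. A list whose members vary together between mice or sorts can thus fall outside them without a genotype effect. The lists hold 490 genes in all, of which 49 had no probe set with a single gene name. They overlap in part. Lists of interferon-gamma inducible, type I interferon inducible and conventional CD4 T cell genes were added after the results of these lists had been seen.

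The lists, the floor, the threshold, the alternatives and the rule for named genes were fixed before the data were examined. The rule names 12 genes per direction with the largest ratios among genes above the floor on both arrays whose other probe sets go the same way. It adds 5 per direction with the largest bounds, up to 4 members of each list with the largest changes of at least 2-fold (or the 2 brightest members if there are none), and 16 genes chosen in advance, 15 of which had a named probe set. Clone names and predicted genes are counted but not named. The rule gave 109 genes. Of these, 35 had another probe set above the floor on both arrays, and in 7 at least 1 such probe set went the other way.

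The number of arrays limits the precision. The only error that can be estimated is the disagreement between probe sets of the same gene: over 3968 genes with at least 2 probe sets above the floor on both arrays, the robust SD of the log2 ratio of a single probe set was 0.36. It contains no variation between mice, sorts or hybridisations.

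The procedure was tested on simulated data that used the WT signals, over 11576 genes. The size of each log2 ratio was drawn at random from probe sets above the floor on both of these arrays. The genes to be changed were drawn from those with a WT signal above 8 times the floor. Recovery of single genes nearer the floor was therefore not tested. Of genes made 4-fold higher or lower (50 each), 98.0% and 94.0% passed the threshold, and of genes made 8-fold higher or lower (50 each) 100% passed in each direction. Unchanged genes passed it in 5.37% of cases, and of 200 unchanged random lists 10 lay outside the middle 95% of matched lists. Neither is an error rate: the first restates the ratios on these arrays, real differences included, and the second follows from how the lists were drawn. Of 200 lists of 20 genes shifted by 0.5 on the log2 scale, 199 lay above the 97.5th percentile. Every member was shifted by the same amount and the members were drawn at random. This therefore does not show how often real lists, whose members change unequally or together, would be found.

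Alternatives were a floor at the 40th or 60th percentile and no floor with a pseudocount of 32. Others were quantile normalization, median-centred ratios and an intensity-dependent loess with a span of 0.4. The median over a gene's probe sets was another, taken only over those above the floor on at least 1 array. The last left out probe sets with names ending in _s_at, _x_at or _a_at. These are called probe sets that can bind several transcripts here, and the transcripts can be variants of the same gene. For the counts, thresholds of 1.5-fold and 3-fold and genes above the floor on both arrays only were added. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.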

Results

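Gene expression was compared between splenic Tregs of DNR mice, in which a dominant negative TGF-beta receptor II interferes with signalling by the cytokine TGF-beta, and splenic Tregs of WT mice. The comparison asks how the transcriptome of Tregs differs between mice that carry this receptor and WT mice. There was 1 array per genotype, so every difference below is between these RNA samples, has no replicate check and cannot be set against the spread between mice. On the DNR array 22518 of 45037 probe sets were above the floor of 110.9 and on the WT array 20367. The floor was the DNR median, so the DNR count was fixed by construction. These counts do not show how many genes each sample expressed. The median signal was 110.9 on the DNR array and 91.0 on the WT array. The log2 signals of the arrays correlated with r = 0.826 across all probe sets and 0.963 across those above the floor on both; probe sets are not independent replicates. The 18 probe sets for bacterial hybridisation spike-ins were all brighter on the DNR array, by 1.95-fold at the median, and the 24 probe sets for poly-A spike-ins by 1.29-fold at the median, with 20 of them brighter.

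Most transcripts had similar signals in both genotypes: of the 9281 genes above the floor on both arrays, 8740 (94.2%) differed by less than 2-fold, 283 were higher in DNR Tregs by at least 2-fold and 258 were lower. With the 2646 genes above the floor on 1 array, 477 were higher and 350 lower. Of the 2646, 1813 were above it on the DNR array alone, whose median was higher, and 833 on the WT array alone. For 2360 of the 2646 the bound was under 2-fold, so the size of their difference is unknown. The 477 and 350 depended on the floor and the threshold. They were 1026 and 550 with the floor at the 40th percentile, 250 and 246 at the 60th, and 1311 and 694 with no floor. At 3-fold 56 genes were higher and 63 lower, so the excess of higher genes turned. Among the 163 genes at least 2-fold different by their brightest probe set that had a second probe set above the floor on both arrays, the second went the same way in 115 (70.6%) and reached 2-fold the same way in 27 (16.6%). A single probe set's value is therefore uncertain. A list median depends less on any 1 probe set, but its members share the variation between mice, sorts and hybridisations. It is thus no stronger evidence of an effect of the genotype. Of 80 named genes with a difference of at least 2-fold, 47 kept it under all 7 alternative settings run for genes, and 33 were below it or had no probe set above the floor under at least 1. Of the 29 gene lists, 10 had a median outside the middle 95% of matched random lists: 7 were higher in DNR Tregs and 3 lower.

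**Figure D1:**
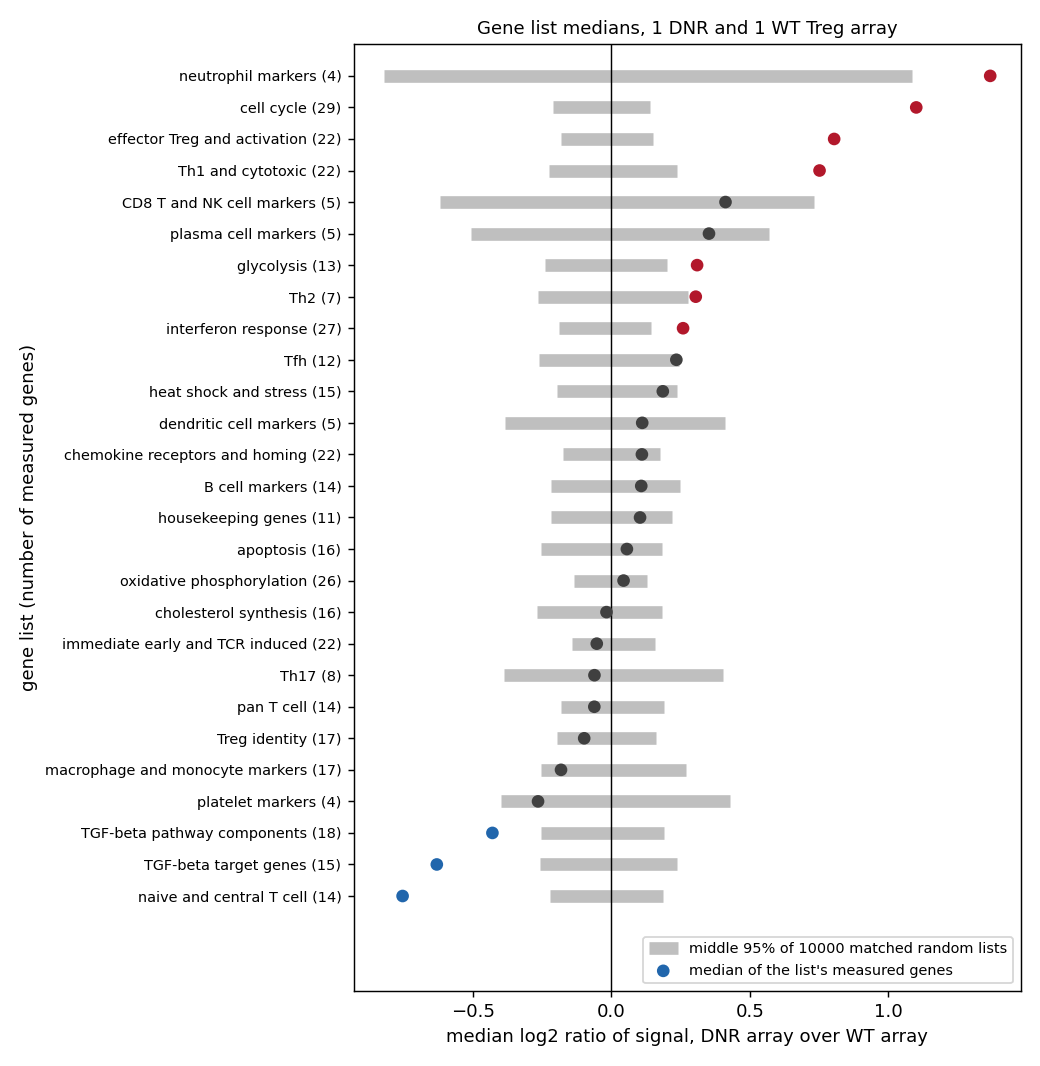
Median log2 ratio of MAS5 signal, DNR over WT array (x axis), for each gene list with at least 4 measured genes (y axis, number of measured genes in brackets). Points are list medians, red above and blue below the middle 95% of 10000 random lists matched on signal (grey bars). The cell cycle (1.10), effector (0.80) and Th1 (0.75) lists lie to the right of their bars, and the naive (-0.75) and TGF-beta target (-0.63) lists to the left.

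Transcripts induced by TGF-beta signalling were lower in DNR Tregs. Of 15 measured TGF-beta target genes, 12 had a lower signal on the DNR array, 6 of them by at least 2-fold, and none was higher by at least 2-fold. The list median was -0.63, a 1.55-fold lower signal, which was below all 10000 matched random lists. Macrophage and monocyte markers also had a lower median, -0.18. In the main setting it lay within the range of matched random lists, at percentile 8.51. Of these markers 15 of 17 were lower, C1qa by 2.39-fold, while C1qb was nearly equal (641 against 652). Skil, a repressor of SMAD transcription factors that TGF-beta induces as a feedback inhibitor, had a signal of 4261 in DNR and 14390 in WT Tregs, 3.38-fold lower. Smad7, the inhibitory SMAD, was 2.99-fold lower (985 against 2948), and its second probe set had a log2 ratio of -0.73. Rgs16, a regulator of G protein signalling, was 3.11-fold lower, and both of its other probe sets were lower by more than 2-fold. All of these probe sets can bind several transcripts. Tsc22d1, known as TGF-beta-stimulated clone 22, was 3.35-fold lower, but its log2 ratio was -0.58 with the median over its probe sets and -0.27 without probe sets that can bind several transcripts. Ldlrad4, which restrains SMAD activation, was at least 3.11-fold lower. Itgae, the integrin chain CD103 that TGF-beta induces on T cells, was 2.64-fold lower (1134 against 2999), with a second probe set at -1.85.

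Components of the TGF-beta pathway were also lower as a list. Of 18 measured genes 16 had a lower signal, but only 3 by at least 2-fold. These were Smurf1, a ubiquitin ligase that acts on SMADs and receptors (4.62-fold lower, at a DNR signal of 135, near the floor), the co-receptor gene Tgfbr3 (3.59-fold lower) and Smad7. The list median was -0.43, at percentile 0.06 of matched random lists. The macrophage marker median of -0.18 was in the same direction, though at percentile 8.51 of matched random lists. The mouse Tgfbr2 probe set was lower in DNR Tregs by a log2 ratio of -0.59 (5457 against 8193). Which sequence the transgene carries is not given in the sources used here, so this probe set does not check the genotype. Tgfb1, the gene of the cytokine itself, was 1.40-fold lower (236 against 331), with a second probe set at -1.30. Zfyve9, a SMAD anchor, was at least 2.40-fold higher, with a log2 ratio of 0.67 at a floor at the 60th percentile.

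The median of the Treg identity genes lay within the range of matched random lists, which does not mean that each member was unchanged. Of the 17 members 3 were lower by at least 2-fold and 0 higher. Of all 11927 measured genes 350 were lower and 477 higher. Of 17 measured genes 8 were higher and 9 lower, and the median of -0.10 lay at percentile 19.6 of matched random lists. It was 0.0938 when the median over each gene's probe sets was used, and -0.21 (percentile 8.25) without probe sets that can bind several transcripts. Foxp3 had a signal of 4550 in DNR and 3754 in WT Tregs, a 1.21-fold difference. Ctla4, an inhibitory receptor of Tregs, was 1.26-fold higher (52119 against 41217) and Ikzf2, which encodes the transcription factor Helios, 1.43-fold higher. Il2ra, the high-affinity chain of the interleukin-2 receptor, was 1.16-fold lower. The 3 members lower by at least 2-fold were Itgae, Nt5e (CD73, which produces adenosine, 2.25-fold) and Izumo1r (folate receptor 4, 2.03-fold). The second probe set of Nt5e had a log2 ratio of 0.10, and Izumo1r was just under 2-fold with each of the other scalings (-0.98 to -0.99). The pan T cell list did not differ (median -0.06, 14 genes), and Cd4 was 1.43-fold lower at a modest signal of 415 against 595.

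Genes of effector Tregs and T cell activation were higher in DNR Tregs. Of 22 measured genes 19 were higher, 7 of them by at least 2-fold, and 1, Itgae, was lower by at least 2-fold. The median of 0.80 was above all 10000 matched random lists. Gzmb, the cytotoxic protease granzyme B, was 7.46-fold higher (13369 against 1793). Cxcr3, a chemokine receptor of type 1 responses, was 3.35-fold higher, Klrg1, a receptor of terminally differentiated Tregs, 2.37-fold higher (13855 against 5848), and S100a6, a calcium-binding protein, had 12496 against 4172. The only probe set of S100a6 can bind several transcripts. Il10, an anti-inflammatory cytokine, was just below the threshold (4468 against 2238). Of 4 measured neutrophil markers 3 were higher too, at low signals. Their median of 1.37 rests on 2 genes at their bound and was 0.10 with the floor at the 40th percentile.

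Genes of naive and central T cells were lower. Of 14 measured genes 13 were lower, 4 of them by at least 2-fold, and the median of -0.75 was below all 10000 matched random lists. Macrophage and monocyte markers were also lower in 15 of 17 cases (median -0.18), though this median lay at percentile 8.51 of matched random lists. Ccr7, the receptor that guides T cells into lymphoid tissue, was 2.47-fold lower (4627 against 11433). Klf2, a transcription factor of quiescent, recirculating T cells, was 2.29-fold lower (7930 against 18152). Actn1, which encodes an actinin, was 2.44-fold lower, with its second probe set at -1.82, and Igfbp4 was 2.23-fold lower although 1 of its 3 other probe sets was higher and the median over its probe sets gave -0.17.

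Th1 and cytotoxic genes were higher. Of 22 measured genes 18 were higher, 8 of them by at least 2-fold, and none was lower by at least 2-fold. The median was 0.75, above all 10000 matched random lists. Gzma, granzyme A, was not above the floor in WT Tregs and at least 12.3-fold higher in DNR Tregs (signal 1361). Its only probe set can bind several transcripts. Ccl5, a chemokine of effector T cells, was 5.94-fold higher (5383 against 906). Ifng, the gene of interferon-gamma, was 2.87-fold higher (3524 against 1227), and Tbx21, which encodes T-bet, the master transcription factor of Th1 cells, 2.59-fold higher (731 against 283). Markers of CD8 T and NK cells were near the floor on both arrays: Klrd1 had 284 against 183 and Cd8b1 171 against 294, and the list median of 0.41 over 5 measured genes lay at percentile 82.4. Neutrophil markers were higher at low signals (percentile 99.8), but 4 of the 12 on the array were measured. Of these, Mmp9 was 2.93-fold higher (537 against 184), Ngp at least 2.59-fold (signal 287) and S100a8 at least 2.57-fold (signal 285). With the floor at the 60th percentile the log2 ratios of Ngp and S100a8 were 0.78 and 0.77, and with the floor at the 40th the list median was 0.10 (percentile 63.6).

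The lists of other helper T cell programmes had smaller medians than the Th1 list in the main setting. The Th2 list had a median of 0.30 over 7 measured genes (percentile 98.6), with Maf, a transcription factor of interleukin-10 and interleukin-4 producing cells, 2.22-fold higher and all 4 of its other probe sets higher by less than 2-fold. Plcd1, a phospholipase, was at least 2.03-fold higher on a probe set that can bind several transcripts, and its log2 ratio was -0.325 without such probe sets. The Th2 list lay within the middle 95% in 4 of the 8 alternatives, with its lowest percentile, 71.1, at a floor at the 40th percentile. With no floor its median was 0.74 (percentile 99.6), near that of the Th1 list in the same setting (0.80). The Th17 median was -0.06 over 8 genes (percentile 38.2), and 0.22 with the floor at the 40th percentile. Ahr, the aryl hydrocarbon receptor, was 3.03-fold lower and Il17re 2.29-fold lower, though with no difference by the median over its probe sets (-0.000585). Il21 was at least 2.07-fold higher, with a log2 ratio of 0.46 at a floor at the 60th percentile. The Tfh median was 0.23 over 12 genes (just within the middle 95% of random lists, which reached 0.25) and lay above it in 5 of the 8 alternatives. Il6ra, the receptor for interleukin-6, was 3.34-fold lower, with a second probe set at -0.48 and -1.11 by the median over its probe sets.

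Cell cycle genes were higher in DNR Tregs, and of the 29 lists this one held the most genes higher by at least 2-fold. Of 29 measured genes 27 were higher, 17 of them by at least 2-fold, and none was lower by at least 2-fold. Across the settings between 11 and 18 were at least 2-fold higher. The lowest median of the list, 0.87, came without probe sets that can bind several transcripts. The median of 1.10 corresponds to a 2.15-fold higher signal and was above all 10000 matched random lists. Mki67, the proliferation marker Ki-67, was 2.74-fold higher (4392 against 1605). Aurkb, a mitotic kinase, was 4.88-fold higher, Birc5 (survivin) 3.50-fold, Cdc20, an activator of the anaphase-promoting complex, 3.48-fold and the spindle motor Kif11 3.08-fold. The other probe sets of Cdc20 and Kif11 were at 0.78 and 0.73, and Cdc20 was under 2-fold without probe sets that can bind several transcripts. Aurkb and Birc5 have only such probe sets. Among the 12 named genes with the largest higher ratios above the floor on both arrays were also Ect2, which directs cytokinesis (4.32-fold), and Ncapg2, a condensin subunit (3.93-fold); Ect2 also has only such a probe set. Of 4 measured neutrophil markers 3 were higher as well, though their median was 0.10 with the floor at the 40th percentile.

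**Figure D2:**
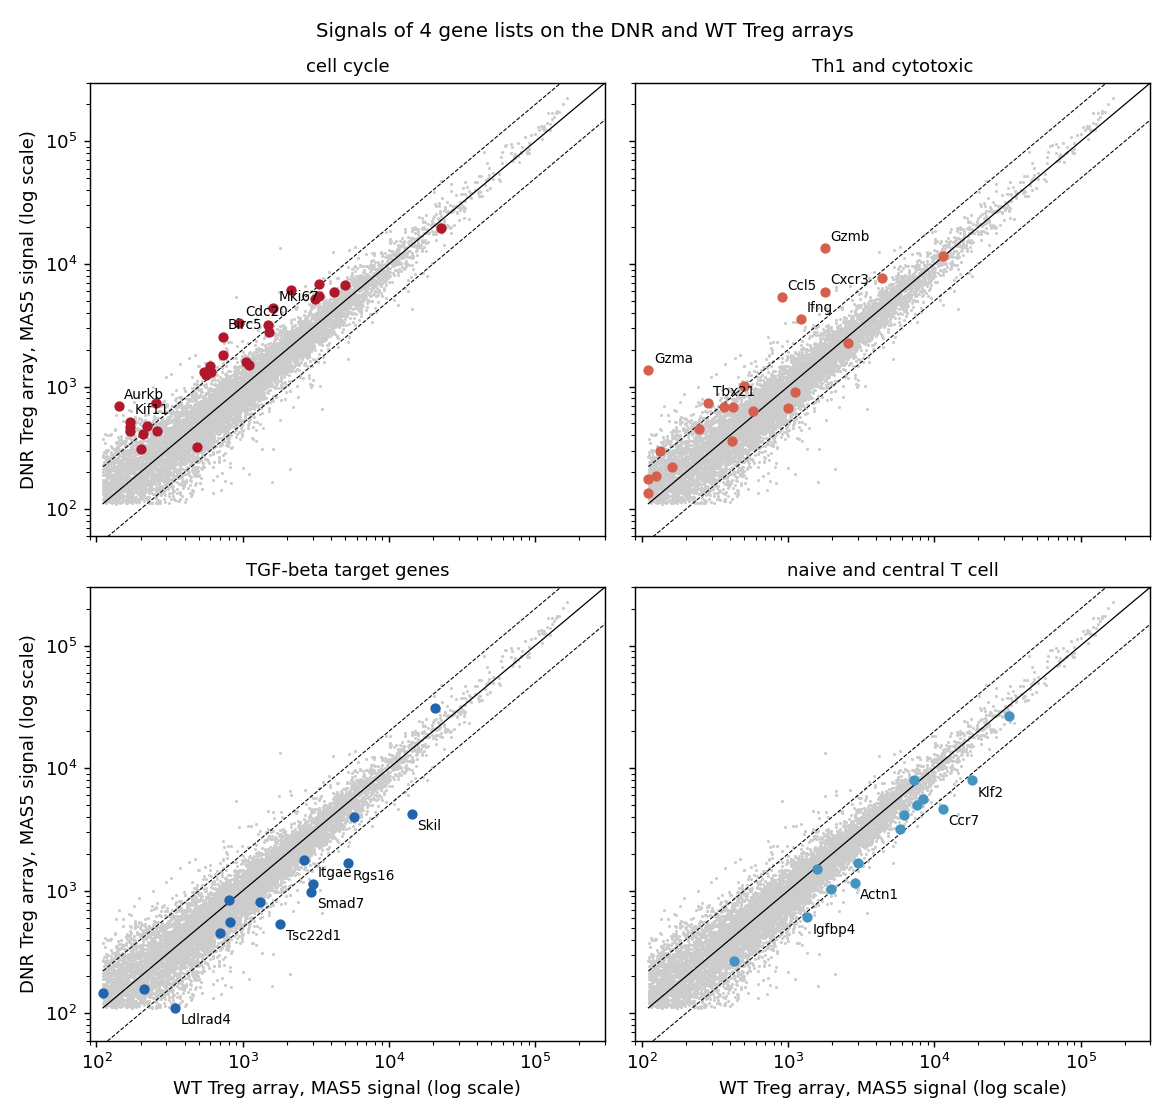
MAS5 signal of each gene on the WT array (x axis, log scale) and the DNR array (y axis, log scale) for 4 gene lists (coloured points, values below the floor set to it) over all genes above the floor on both arrays (grey points). The solid line marks equal signals and the dashed lines a 2-fold difference, beyond which lie Gzmb (13369 against 1793) on the upper side and Skil (4261 against 14390) on the lower.

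Interferon response genes were higher by a small amount, with a median of 0.26 over 27 measured genes (percentile 99.95). Of these 18 were higher, 3 by at least 2-fold: Iigp1, an immunity-related GTPase (3.10-fold), the chemokine gene Cxcl10 (3.01-fold) and the guanylate-binding protein gene Gbp2 (2.16-fold, with a second probe set at 0.66). Ifit3 was 2.36-fold lower. With the median over the probe sets of each gene the percentile of this list was 96.7.

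Chemokine receptors and homing molecules went both ways, with a list median of 0.11 over 22 measured genes (percentile 89.7). At least 2-fold lower were 5 genes: Gpr15, a receptor that guides T cells to the large intestine (at least 3.86-fold), Itgae, Ccr7, Ccr9, a receptor for homing to the small intestine (2.27-fold), and Cxcr4 (2.01-fold). At least 2-fold higher were 3 genes: Cxcr3, Ccr1 (at least 2.70-fold) and Cx3cr1 (at least 2.03-fold). Cxcr4 and Cx3cr1 are named after their values were seen. Ccr9 had a second probe set at -0.51 and none above the floor once probe sets that can bind several transcripts were left out. Cxcr4 was just under 2-fold with each of the other scalings (-0.98 to -0.99), and with the floor at the 60th percentile Ccr1 and Cx3cr1 were at 0.84 and 0.43. Without probe sets that can bind several transcripts the list lay just above the middle 95%, with a median of 0.15.

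Large differences were also found in other genes. Sox4, a transcription factor gene that TGF-beta induces in T cells, had a signal of 211 in DNR and 2092 in WT Tregs, 9.91-fold lower. Cnn3 (calponin 3) was 9.56-fold lower, and both of its other probe sets were lower by more than 3-fold. The glutathione transferase gene Gsta4 was 5.26-fold lower, the sialyltransferase genes St8sia6 and St8sia1 5.24-fold and 4.40-fold, Golm2 5.09-fold, the adaptor gene Shc1 4.96-fold, Cd24a 4.57-fold and Ctsw, a cathepsin, 4.36-fold. Prickle1 was 3.71-fold and the kinase gene Sgk3 3.67-fold lower. With the median over their probe sets the log2 ratios were smaller: -1.78 for Sox4, -2.02 for Cnn3, -1.11 for Golm2, -1.01 for Shc1, -0.76 for St8sia1 and -0.80 for Sgk3. Prg4, lubricin, was above the floor on the WT array alone and at least 15.9-fold lower. Bcl2l12 (at least 4.61-fold), Trmo (at least 4.25-fold), Zbtb6 (at least 4.04-fold) and Socs6 (at least 4.93-fold, with another probe set at 0.49) were likewise above the floor in WT Tregs alone, and Bcl2l12 was at -1.16 by the median over its probe sets. All bounds are smaller with a higher floor by construction. Higher in DNR Tregs were Baiap3 (4.49-fold), Tgm2, transglutaminase 2 (4.14-fold, all 4 other probe sets above the floor on both arrays higher), Clip4 (4.06-fold), the inflammasome receptor gene Naip2 (1189 against 297), Mt1, a metallothionein (3.96-fold), Bak1, a pro-apoptotic BCL2 family member (3.85-fold), and Apcdd1 (3.84-fold). With the median over their probe sets Bak1 was at 1.12, Tgm2 at 1.29 and Apcdd1 at 1.07. Apcdd1, Clip4, Mt1, Naip2 and Tgm2 rest on probe sets that can bind several transcripts and had no probe set of another kind above the floor. Asns (asparagine synthetase, at least 4.74-fold), Cysrt1 (at least 4.84-fold), Ttn (at least 4.54-fold) and Ppic (at least 3.86-fold) were above the floor on the DNR array alone. The same limit held for Cysrt1, and Ttn was at 0.58 with the median over its probe sets.

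Most marker lists of other splenic cells lay within the range of random lists, though some of their genes had high signals on both arrays. The brightest B cell marker, Ighm, had 19368 against 15236, and the dendritic cell marker Cst3 2800 against 2559. Of 19 B cell markers on the array 14 were measured, while Cd79a, Blnk, Pax5, Ebf1 and Cr2 were not above the floor on either array. Of 11 dendritic cell markers 5 were measured, while Flt3, Zbtb46, Xcr1, Batf3, Cd209a and Clec10a were not above it. All of these genes are named after their values were seen. B cell markers had a median of 0.11 over 14 measured genes (percentile 77.1), with Cd22 2.74-fold higher at 444 against 162. Plasma cell markers had a median of 0.35 over 5 genes (percentile 50.3), with Igha at 494 against 255 and Jchain at 193 against 195. Macrophage and monocyte markers had a median of -0.18 over 17 genes (percentile 8.51), with 15 of the 17 lower. The list lay below the middle 95% of random lists in 3 of the 8 alternatives (percentiles 1.32, 1.92 and 2.48). At least 2-fold lower were 3 genes: C1qa (2.39-fold), C1qc (2.08-fold) and Vcam1 (2.04-fold, just under 2-fold with the other scalings). Dendritic cell markers had a median of 0.11 over 5 genes (percentile 73.9), with Ccr9 the member lower by at least 2-fold, platelet markers -0.27 over 4 genes (percentile 9.25) and erythroid markers -0.21 over 2 genes (percentile 29.4). Xist, the RNA expressed from the inactive X chromosome of females, had signals of 22840 and 22404, and the 3 Y-linked genes named on the array were not above the floor on either. Housekeeping genes had a median of 0.10 over 11 genes (percentile 83.6), with Eef1a1 1.21-fold higher. Their median was -0.13 when probe sets that can bind several transcripts were left out.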

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

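With 1 array per genotype, neither an unusual replicate nor a difference between strata can be looked for. Comparing lists with matched random lists was fixed before the data were examined, but its use against scaling, and the tests on other cells, effector and naive Tregs, were chosen after the results were seen. The genes of the conventional CD4 T cell list had not been looked at, but the Treg identity median used with it had.

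The hybridisation spike-ins, outside the main measurement, were 1.95-fold brighter on the DNR array at the median (1.65-fold to 2.21-fold over 18 probe sets). The 3′ probe set of the Actb control had a log2 ratio of 0.33 and its 5′ probe set -0.01, and those of the Gapdh control 0.27 and 0.13. Within each array the 3′ signal was the brighter. For Actb it was 93899.6 against 14881.9 at the 5′ end on the DNR array, and 74496.5 against 14950.4 on the WT array. For Gapdh it was 13953.9 against 6125.49 on the DNR array, and 11557.3 against 5580.49 on the WT array. Among 4046 probe sets above the floor on at least 1 array but without a single gene name, 216 were at least 2-fold higher in DNR Tregs and 81 lower. 1 of the higher ones, singled out after its values were seen, had a signal of 12426 against 1102.

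Cell cycle genes were higher in DNR Tregs (median 1.10). If spike-ins were added in equal amounts, their brightness after scaling is consistent with a weaker sample signal on the DNR array, but scaling that depends on signal would move random lists of like signal as well, and their middle 95% ended at 0.139; effects of single probes or of RNA quality are not covered. Dividing cells of another splenic type, which the sort should remove, cannot be told apart: of 8 marker lists the neutrophil list had the highest median, 1.369, over 4 genes at low signals, 2 of them at their bound, and only 2 of the lists had at least 10 measured genes. A larger share of effector-type Tregs is a candidate explanation that the data allow, since the effector list was higher (0.805) while the naive list was lower. Whether the genotype causes the difference at all, and if so through division in each cell or the mix of Treg states, stays open.

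Th1 and cytotoxic genes were higher (median 0.75), and the middle 95% of random lists of like signal ended at 0.237, which argues against signal-dependent scaling as the whole cause. CD8 T or NK cells in the sort, which the CD4 gate should remove, cannot be told apart, since the median of their markers, 0.412, comes from 5 genes near the floor of which 3 were higher and 2 lower. Conventional CD4 T cells that produce these transcripts cannot be told apart from Tregs either: 5 of 9 marker genes of conventional CD4 T cells were measured and their median was 0.0074, yet a small share of cells with very high granzyme would hardly move them. A direct effect of the genotype in Tregs is untested.

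TGF-beta target genes were lower (median -0.63), and the middle 95% of random lists of like signal began at -0.258, which argues against signal-dependent scaling as the whole cause. A loss of naive-type Tregs, whose genes had a median of -0.755, cannot be told apart from a direct loss of TGF-beta signalling, because genotype and cell state differ together between the arrays. The impaired receptor that the design names stays open as the biological explanation.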

How the results depend on the processing

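The number of arrays limits all of these values, and the signal limits them most near the floor, where 395 of the 477 higher and 269 of the 350 lower genes had a mean log2 signal below the median of measured genes. The counts of genes higher and lower by at least 2-fold depended on the floor: 1026 and 550 with the floor at the 40th percentile, 250 and 246 at the 60th, 1311 and 694 with no floor and a pseudocount of 32, and 283 higher among genes above the floor on both arrays. At thresholds of 1.5-fold and 3-fold they were 1526 and 1175, and 56 and 63. The share of higher genes among these calls was 57.7%, 65.1% and 50.4% with the floor at the 40th and 60th percentile, 65.4% with no floor, 47.1% at 3-fold, and between 53.2% and 62.3% with the scalings. Scaling moved the median of the genes above the floor on both arrays by at most 0.03. Of the 10 lists outside the middle 95% of random lists, 6 stayed on the same side under all 8 alternatives: the effector, naive, TGF-beta pathway, TGF-beta target, Th1 and cell cycle lists. The Th2 list stayed outside in 4 of the 8, and the interferon, glycolysis and neutrophil lists in 7 each. Of the lists inside, Tfh lay above the middle 95% in 5 of the 8, the macrophage list below it in 3 and the chemokine receptor list above it in 1. No paired analysis was possible because there was 1 array per genotype, and for the same reason no array could be left out.

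List medians moved by more than 1 SD of matched random lists in 25 of 232 values, and the cause was not tested. Without probe sets that can bind several transcripts the medians were -0.21 (Treg identity), 0.70 (effector), 0.87 (cell cycle), -0.22 (heat shock), -0.0075 (plasma cell), 0.38 (sex-linked) and -0.13 (housekeeping). With the median over a gene's probe sets they were 0.0938 (Treg identity), 0.13 (interferon), -0.0642 (heat shock), 0.0474 (CD8 T and NK) and 0.38 (sex-linked). With the floor at the 40th percentile they were 0.12 (Th2), 0.22 (Th17) and 0.10 (neutrophil), and at the 60th 0.717 (effector), 0.0575 (plasma cell), 0.78 (neutrophil) and -0.0443 (platelet). With no floor they were 0.74 (Th2), 0.87 (plasma cell), 0.73 (erythroid) and -0.50 (platelet), and with quantile normalization -0.0225 (heat shock) and -0.49 (platelet). Of 746 values of named genes 675 moved by less than the SD between probe sets. Of the others 69 moved by more, 52 of them towards 0, and 2 reversed. Both reversals came without probe sets that can bind several transcripts: Plcd1 (-0.325) and Socs6 (0.49). Of 80 named genes at least 2-fold different, 47 stayed so under all 7 alternatives run for genes; without probe sets that can bind several transcripts, Apcdd1, Aurkb, Birc5, Ccr9, Clip4, Cysrt1, Ect2, Gzma, Igfbp4, Izumo1r, Mt1, Naip2, Rgs16, S100a6, S100a8 and Tgm2 had no probe set above the floor.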

Other observations

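The interferon hypothesis and its lists were chosen after the results above were seen, and the test was set before the values of its own genes were looked at.

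Glycolysis genes were slightly higher, with a median of 0.31 over 13 measured genes, 11 of them higher and none by 2-fold (percentile 99.7 of matched random lists, and 93.6 without probe sets that can bind several transcripts). Among them were Pgk1, phosphoglycerate kinase, 1.40-fold and Ldha, lactate dehydrogenase A, 1.11-fold higher. Oxidative phosphorylation and cholesterol synthesis genes lay within the range of random lists. The former had a median of 0.04 over 26 genes (percentile 78.9) and the latter -0.02 over 16 genes (percentile 61.4). Of 16 measured apoptosis genes, whose median was 0.06 (percentile 80.0), Bak1 was 3.85-fold higher (1.12 on the log2 scale by the median over its probe sets), while the BH3-only genes Bbc3 (PUMA) and Bcl2l11 (BIM) were 2.43-fold and 2.38-fold lower, the latter with a second probe set at -1.15. Immediate early and T cell receptor induced genes had a median of -0.05 over 22 genes (percentile 20.4), and 1, the phosphatase gene Dusp2, was at least 2-fold lower (2.04-fold, and just under 2-fold with median-centred ratios). Heat shock and stress genes had a median of 0.19 over 15 genes (percentile 93.6), which was below 0 in 3 settings: quantile normalization (-0.0225), the median over probe sets (-0.0642) and without probe sets that can bind several transcripts (-0.22).

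The higher interferon genes Iigp1 and Gbp2, beside a higher Ifng and a lower Ifit3, led to the hypothesis that the difference may follow interferon-gamma rather than type I interferon. It was tested on genes outside the earlier list. Of 13 measured interferon-gamma inducible genes 12 were higher, with a median of 0.53 above all 10000 matched random lists. Only Cd274, the gene of PD-L1, reached 2-fold (2.41-fold), and it is named after its value was seen. Of the 15 measured type I inducible genes 9 were higher and 6 lower. Their median of 0.21 was smaller, but it too lay above the middle 95% of matched random lists, which ended at 0.18 (percentile 98.38). The prediction that the type I genes would stay within the range was therefore not met. Both lists were run in the main setting only, without the alternatives.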
